A study of Homo sapiens with 8 samples.

How the data were processed

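Total RNA from H1 and H9, established lines of human embryonic stem cells, was hybridised as biotin-labelled cRNA to Affymetrix Human Genome U133 Plus 2.0 arrays, 1 sample per array. Each line was represented in 2 states with 2 arrays per state, which the labels call biological replicates. Undifferentiated cells were kept in mTeSR1, a defined medium for pluripotent stem cells. Embryoid bodies (EB), which are floating aggregates in which the cells begin to differentiate, were made from dissociated cells on low-attachment plates for 3 days, in a medium without bFGF and with 10 µM of the compound Y-27632. State therefore changes together with medium and attachment, and the labels name the compound and the absence of bFGF for EB, saying nothing of the compound in undifferentiated cultures. The labels do not say which cultures the replicates came from, so a p-value measures only the spread between these samples.

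The deposited values are intensities on a linear scale, 1 per probe set and array, made with MAS5 per the submitters' processing notes, with the version not given in the sources used here. The trimmed mean of each array, leaving out 2% at each end, was 500.1 on each of the 8, so every array had been scaled to the same target before deposit. Median intensities over all probe sets lay between 68.7 and 86.0. Detection calls were not used here, and the limit below which an intensity is background is therefore unknown; a probe set is called dim in a group of arrays when it is below the median of its own array on each of them. For genes dim on one side of a comparison, the bright side's mean is set against the higher of the array median and the dim probe set's own value, and the result is given as "at least N-fold". MAS5 subtracts mismatch probes, which makes low values noisy, and scaling to one mean forces the average change across an array towards 0.

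The table holds 54675 probe sets, 62 of them manufacturer's controls. The platform annotation gave a single gene symbol for 41091 probe sets and several for 1801, while 11721 probe sets are unnamed here. Entrez identifiers of 41037 probe sets matched the gene table of the reference, and 0 symbols changed by that match. No gene was named from a probe set with several symbols. The pluripotency factor POU5F1 has only such a probe set and is not reported. Among named genes, APOA1, PRSS2, CXCL5, AIF1, PERP, KRT8, CDH11, IDI1, CNN2, ZNF680 and TRIM61 were read by probe sets of a type that can cross-hybridise with related transcripts. Each of 19775 genes was represented by its probe set with the highest mean log2 value over the 8 arrays. A gene was tested when this probe set was above its array's median on at least 2 arrays, which left 14056 genes.

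Intensities were transformed as log2(value + 16), so fold changes of low genes are understated. All 8 arrays entered one fit of 4 group means in limma 3.58.1 (R 4.3.3; lmFit, then eBayes with trend and robust settings) with 4 residual degrees of freedom. Contrasts were EB minus undifferentiated averaged over the lines, the same within each line, the difference of the EB effect between H9 and H1, and H9 minus H1 in each state. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. Changes are given on the log2 scale with the standard error (SE) of the fit.

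A total of 25 gene lists were written before the data were examined. They cover core and naive pluripotency, NODAL, FGF-ERK, WNT, BMP and retinoid signalling, the germ layers, neural crest, trophoblast, surface ectoderm, epithelial to mesenchymal genes, matrix, cell cycle, p53 targets, hypoxia, cholesterol synthesis, actin and YAP targets, dissociation stress, blood and mature tissue markers, and housekeeping genes. They were tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, then with an estimated correlation and with fry. The rule for named genes, also set before, took the 12 largest changes per direction among genes called in the mean EB contrast whose EB and undifferentiated arrays did not overlap in either line, POU5F1, SOX2 and NANOG, the 4 members of each list with the smallest p, the 6 largest differences of the EB effect per direction, and the 8 largest differences between undifferentiated lines per direction. Genes used to tell the sex of a line were left out of all named results.

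Alternatives chosen together with the lists were quantile normalization, added values of 1 and 64, no filter or a filter on the mean, the mean of all probe sets of a gene, all probe sets one by one, eBayes without trend and robust, a minimum log2 change of 1, no line term, fits on part of the arrays, a replicate block, and leaving out each array in turn. Centring each array on its median, and leaving out both arrays labelled H9 EB, were chosen after seeing the data. Values for 14056 genes were also simulated with independent normal noise. Only 67, 67 and 66 of the brighter genes were changed, by 0.5, 1 and 2 on the log2 scale. In the mean EB contrast 53.7%, 88.1% and 98.5% of these were recovered, with 4 false calls. Far more genes were called in the data, and dim genes and correlated errors were not simulated, so these figures are not error rates of the real calls. The weighted co-expression networks named in the study's design text were not run, since 8 arrays in 4 tight groups give no correlations within a group. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.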

Results

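Expression was measured on 8 arrays, 2 for each of undifferentiated H1, H1 EB, undifferentiated H9 and H9 EB. The study's title and design text name a gene signature of self-renewal shared by both lines as its subject, so the comparisons are EB against undifferentiated cells, in both lines and in each, and H9 against H1. Across 14056 tested genes, arrays of the same group correlated at r = 0.991 to 0.992, arrays of the same state from different lines at 0.972 to 0.983, and arrays of the same line in different states at 0.906 to 0.914. The arrays labelled H9 EB correlated with undifferentiated H1 at 0.912 to 0.915 and with undifferentiated H9 at 0.906 to 0.910, and H1 EB with undifferentiated H1 at 0.911 to 0.914 and with undifferentiated H9 at 0.901 to 0.903. These are correlations across genes, which are not independent replicates. The number of arrays limits the precision. The ratio of 3' to 5' GAPDH control signal was 0.936 ± 0.0030 (SD, n = 2) in undifferentiated H1, 0.878 ± 0.013 in H1 EB, 0.869 ± 0.029 in undifferentiated H9 and 0.941 ± 0.034 in H9 EB.

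**Figure D1:**
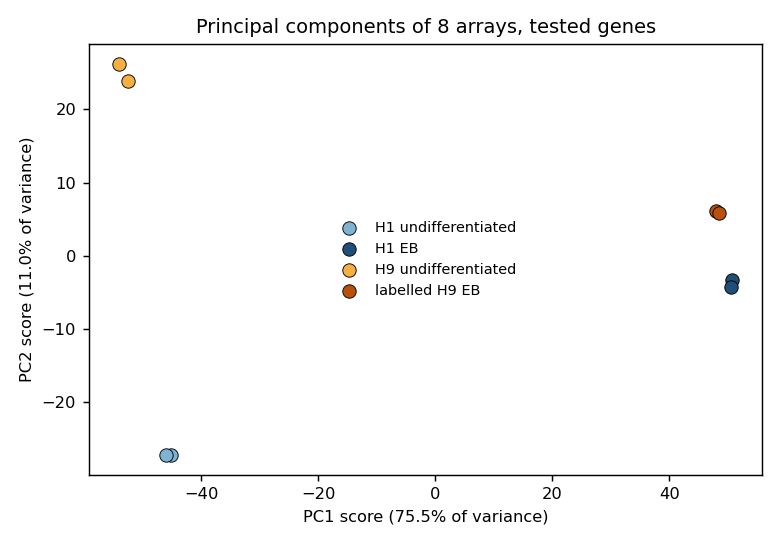
Scores of the 8 arrays on the first and second principal components of log2(signal + 16) over the tested genes, with the share of variance on each axis and colours for the 4 groups. The first component, with 75.5% of the variance, parts EB from undifferentiated arrays, and the second, with 10.95%, sets undifferentiated H1 and H9 farther apart than the EB arrays of the lines.

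The arrays labelled H9 EB had clear signals for some genes that were dim in undifferentiated H9. A set of 5 genes was chosen that were dim in undifferentiated H9 and changed by less than 0.5 on the log2 scale in H1. They also had to be lower in undifferentiated H9 than in undifferentiated H1 by at least 2 on the log2 scale, at a limma adjusted p under 0.05. Their signal in undifferentiated H1 had to exceed 2 times the mean of the array medians. On the arrays labelled H9 EB the signal of these 5 genes stood at 18.4% to 31.6% of the H1 EB level above undifferentiated H9, with a median of 25.05%. With the array median in place of the dim signal of undifferentiated H9 the range was 11.3% to 31.1%. CRYZ, a quinone oxidoreductase, read 3839 in undifferentiated H1, 4334 in H1 EB, 40.1 in undifferentiated H9 and 1395 on the arrays labelled H9 EB. TYW3, TRIM61, CXCL11 and ZNF680 were the other members, and CRYZ and TYW3 are neighbours in the genome, so the 5 genes are 4 loci. With the limit on the change in H1 set at 1 and the other limits kept, 9 genes qualified and their shares ran from -6.0% to 240%. In a check of identity, 2 of the 8 libraries did not match their group's labels. The group is called the arrays labelled H9 EB, and each result that uses these arrays is open to this; limits for this choice of genes were set after the pattern was seen.

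**Figure D2:**
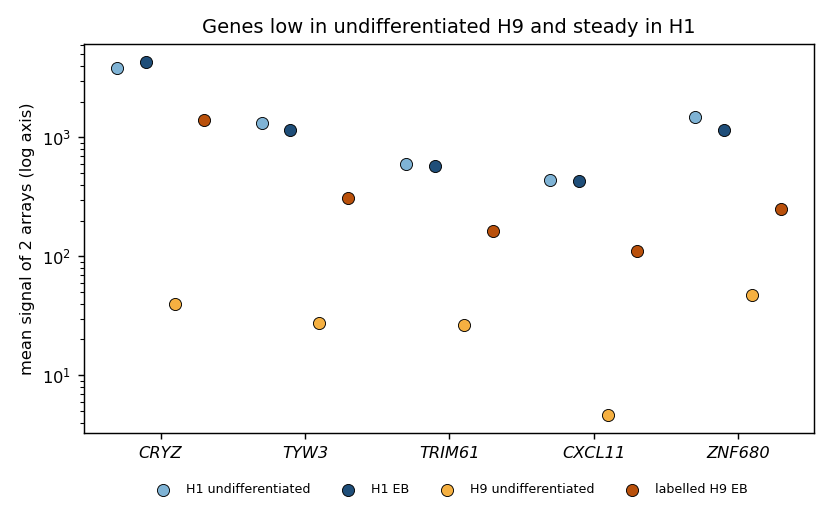
Mean signal of 2 arrays per group, on a log axis, for the 5 genes chosen as steady in H1, dim in undifferentiated H9 and lower there than in undifferentiated H1 by at least 2 on the log2 scale. On the arrays labelled H9 EB all 5 lie between undifferentiated H9 and H1, at 18.4% to 31.6% of the H1 EB level, both taken above undifferentiated H9.

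Averaged over the lines, EB showed a strong rise of genes of endoderm. Of 19 tested endoderm genes 18 rose and 1 fell, with a median log2 change of 3.29. APOA1, APOA2 and APOB, which encode apolipoproteins, rose by 6.59 ± 0.19, 6.27 ± 0.076 and 5.49 ± 0.12 (SE). AFP, encoding alpha-fetoprotein, rose by 5.49 ± 0.061, its signal going from 229 to 14567 in H1 and from 164 to 6079 on the arrays labelled H9. TTR, which encodes transthyretin, rose by 6.11 ± 0.33, and CXCR4, a chemokine receptor used as an endoderm marker, by 4.07 ± 0.076. Outside the list, the fibrinogen genes FGB and FGG were dim in undifferentiated cells and rose at least 40.1-fold and 21.2-fold, LINC00261 at least 28.9-fold, PRSS2 at least 23.1-fold and DEFA6 at least 15.2-fold. GASK1B rose by 5.55 ± 0.072. The endoderm list passed camera (adjusted p = 1.81e-08), but not with an estimated correlation (adjusted p = 0.0540).

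Genes of the core pluripotency list fell moderately. Of 25 tested, 24 fell and 1 was not called, with a median of -0.72 (camera adjusted p = 2.94e-09; 0.0427 with an estimated correlation). NANOG fell by 0.90 ± 0.039, with its signal still at 4599 in H1 EB and 4618 on the arrays labelled H9 EB. Larger falls were seen for POLR3G, encoding a subunit of RNA polymerase III (-1.37 ± 0.042), USP44, a deubiquitinase gene (-1.34 ± 0.044), GAL, the galanin gene (-1.28 ± 0.043), and SEPHS1 (-1.17 ± 0.035). SOX2 changed by -0.21 ± 0.042 (limma adjusted p = 0.00103), by -0.41 in H1 and by -0.0050 on the arrays labelled H9. Its call was lost with quantile normalization, where the change was -0.0045 (adjusted p = 0.903), and without a term for the line (adjusted p = 0.0588), in a range over 19 alternatives from 2.20e-05 to 0.903. The naive pluripotency list did not pass camera (adjusted p = 0.649) but passed fry (adjusted p = 3.33e-05). Of its 10 members 4 rose and 4 fell, led by TBX3, a transcription factor gene also active in mesoderm and amnion (4.60 ± 0.084), and KLF5 (1.51 ± 0.15), against NR5A2 (-1.45 ± 0.13). FGF4 (1.09 ± 0.10) lost its call without the arrays labelled H9 EB, where the change was 0.34 (adjusted p = 0.0793, the highest of 19 alternatives, from 1.86e-06). The naive list's median of 0.096 turned to -0.11 with quantile normalization.

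**Figure D3:**
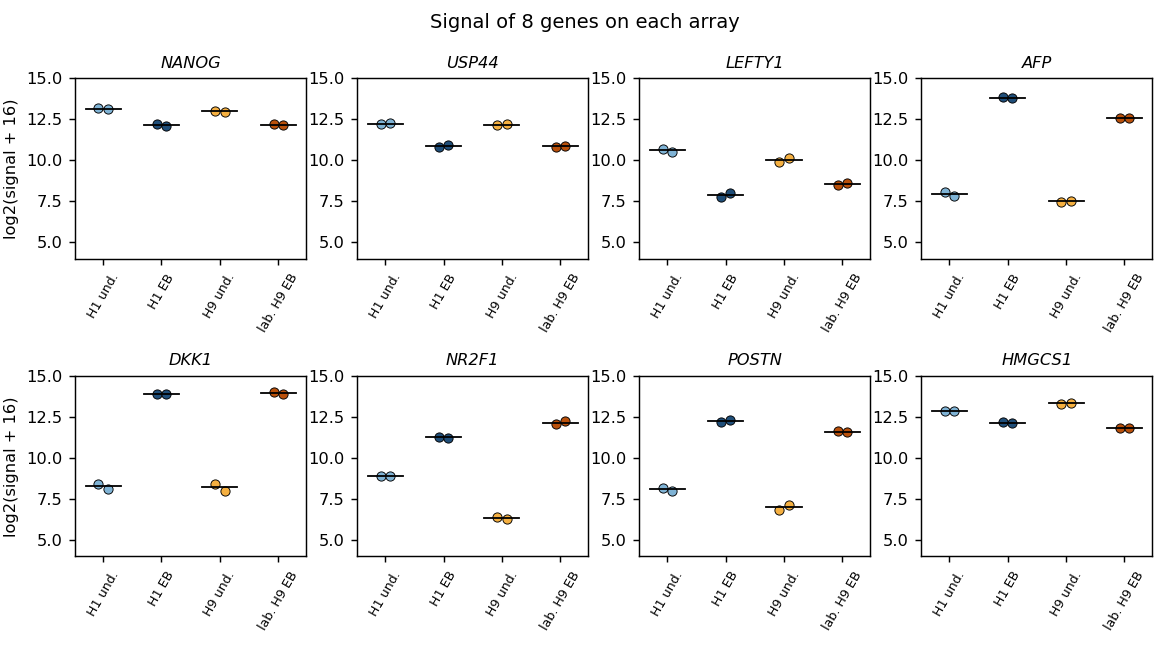
log2(signal + 16) of 8 genes on each array, with points for arrays, lines for the mean of 2 arrays, and the 4 groups along the horizontal axis. NANOG, USP44, LEFTY1 and HMGCS1 are lower in EB in both lines and AFP, DKK1, NR2F1 and POSTN are higher, with arrays of one group close together.

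The largest falls were outside the lists. PLA2G4C, a phospholipase gene, fell by 3.41 ± 0.094, and the changes were -3.23 ± 0.14 for NPTX1, encoding a neuronal pentraxin, and -3.05 ± 0.053 and -2.46 ± 0.087 for the chemokine genes CXCL5 and CXCL6. CUZD1 (-2.73 ± 0.085), P2RY1, a purine receptor gene (-2.67 ± 0.080), D21S2088E (-2.40 ± 0.11), LINC00458 (-2.39 ± 0.042) and LCK, a tyrosine kinase gene (-2.39 ± 0.049), fell as well. AIF1, TDRG1 and SLC30A3 were dim in EB and fell at least 3.3-fold, 2.5-fold and 2.4-fold.

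Signalling genes moved in different directions. In the BMP list 15 of 16 rose, with a median of 2.26 (camera adjusted p = 8.86e-09; 0.0427 with an estimated correlation). They include the ligand gene BMP2 (3.08 ± 0.065), the target gene ID4 (2.19 ± 0.047) and the antagonist genes BAMBI (2.34 ± 0.036) and GREM1 (3.52 ± 0.068). In the WNT list 12 of 16 rose and 2 fell, with a median of 1.53 (adjusted p = 0.000122; 0.0504 with an estimated correlation). It includes the antagonist genes DKK1 (5.70 ± 0.093) and FRZB (3.94 ± 0.070), the transcription factor gene LEF1 (3.20 ± 0.077) and the receptor gene LGR5, which was dim in undifferentiated cells and rose at least 24.9-fold. All 12 tested retinoid and HOX genes rose, with a median of 1.58 (adjusted p = 4.48e-05; 0.0540 with an estimated correlation), among them MEIS2 (3.44 ± 0.077), RBP4 (at least 22.3-fold), MEIS1 (at least 7.5-fold) and HOXB3 (at least 3.7-fold). Without the filter on dim genes the median of this list was 1.08. The NODAL list did not pass camera, which gave its direction as down (adjusted p = 0.401), while fry called it up (adjusted p = 0.00040). Of its 10 members 3 rose and 6 fell, and its median of -0.32 (-0.18 with quantile normalization, -0.49 with centred arrays) and mean of 0.047 differ in sign. LEFTY1, a NODAL antagonist and target, fell by 2.09 ± 0.090, FOXH1 fell by 0.70 ± 0.049, and FST, the follistatin gene, rose by 3.38 ± 0.039. TGIF1 fell by 0.58 ± 0.041 with its brightest probe set, while 1 of its 3 tested probe sets rose and the mean of all gave 0.099 (adjusted p = 0.270, the highest of 19 alternatives, from 1.60e-08). The FGF-ERK list did not pass camera either (adjusted p = 0.122) but passed fry (adjusted p = 1.77e-06), with 13 of 22 lower and 7 higher. MYC fell by 1.48 ± 0.051 and SPRY4, a feedback inhibitor, fell by 1.39 ± 0.055, while the phosphatase gene DUSP4 rose by 2.15 ± 0.076 and IL17RD by 0.76 ± 0.037.

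Markers of several lineages rose together. List members that did not pass the filter on dim genes are left out of these counts. Without that filter the median went from 1.84 to 1.18 for trophoblast and amnion and from 1.05 to 0.44 for mesoderm. Both lists still passed camera (adjusted p = 0.00075 and 0.0319). For primitive streak the median went from 1.61 to 0.24. Of 21 neuroectoderm genes 19 rose, with a median of 2.10 (camera adjusted p = 2.94e-09; 0.0453 with an estimated correlation), including NR2F1, a nuclear receptor gene (4.11 ± 0.063), DLK1 (3.86 ± 0.067), MAP2 (2.68 ± 0.065) and the N-cadherin gene CDH2 (2.10 ± 0.035). Of 13 neural crest genes 10 rose and 3 fell, with a median of 1.69 (adjusted p = 0.00543; 0.0657 with an estimated correlation, and 0.0607 at the preset correlation without the arrays labelled H9 EB). TFAP2A rose by 4.12 ± 0.071, MSX1 by 3.72 ± 0.10, PAX3 by 3.32 ± 0.12 and TFAP2B by 3.18 ± 0.12. Of 15 mesoderm and cardiovascular genes 10 rose and 1 fell (adjusted p = 0.0272; 0.104 with an estimated correlation, and 0.0544 without the arrays labelled H9 EB). PDGFRA rose by 3.87 ± 0.096, HAND1 by 2.94 ± 0.12 and ISL1 by 2.73 ± 0.13, and KDR, encoding a VEGF receptor, fell by 0.82 ± 0.055. Of 14 trophoblast and amnion genes 9 rose and 2 fell (adjusted p = 0.00269; 0.0558 with an estimated correlation), including GATA3 (3.84 ± 0.097) and SLC40A1 (at least 7.7-fold). TFAP2A, TBX3, HAND1, ISL1, GATA3, MSX1, SP5 and CDH2 each stand in more than one list. Of 12 surface ectoderm and keratin genes 9 rose and 1 fell (adjusted p = 0.00170; 0.0558 with an estimated correlation), with DSP up by 1.05 ± 0.047, KRT19 by 1.16 ± 0.039, KRT8 by 0.85 ± 0.042 and PERP by 0.88 ± 0.035. Of 9 primitive streak genes 5 rose and 1 fell, with SP5 up by 2.62 ± 0.092, APLNR by 3.59 ± 0.24 and EOMES by 1.61 ± 0.068. This list passed narrowly (adjusted p = 0.0460), and its call was lost with an estimated correlation (adjusted p = 0.135), with quantile normalization (adjusted p = 0.0741), without the filter on dim genes (adjusted p = 0.0767), without H1 EB replicate 1 (adjusted p = 0.0535), without undifferentiated H9 replicate 1 (adjusted p = 0.0663) and without the arrays labelled H9 EB (adjusted p = 0.192), in a range over 14 alternatives other than fry from 0.0210. FGF8 rose by 1.93 ± 0.20, but the change was 0.62 without those arrays (adjusted p = 0.149, the highest of 18 alternatives, from 5.75e-06).

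All 26 tested matrix genes rose, with a median of 1.75 (camera adjusted p = 9.10e-14; 0.0558 with an estimated correlation). POSTN, encoding periostin, rose by 4.39 ± 0.086, TNC, encoding tenascin C, by 3.03 ± 0.072, COL2A1 by 2.26 ± 0.046 and COL5A2 by 1.77 ± 0.044. Of 16 epithelial to mesenchymal genes 11 rose and 5 fell (adjusted p = 0.0177; 0.0902 with an estimated correlation). The repressor genes ZEB1 and ZEB2 rose by 3.48 ± 0.10 and 3.27 ± 0.12 and the cadherin gene CDH11 by 2.60 ± 0.055.

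**Figure D4:**
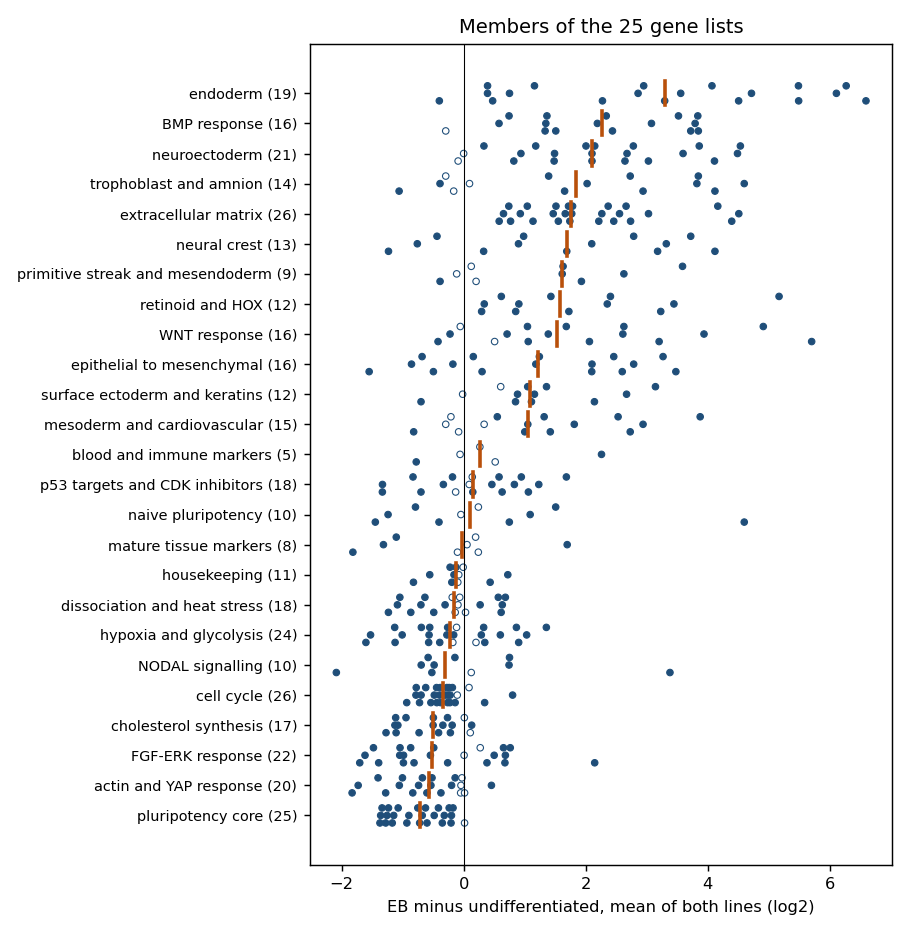
Change of each tested member of the 25 lists in log2 units, EB minus undifferentiated as the mean of both lines, with the number tested in brackets. Filled points passed the gene test, open points did not, and bars mark medians, from 3.29 for endoderm to -0.72 for core pluripotency.

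Cell cycle, cholesterol and actin genes were lower in EB. State changed together with medium and attachment, and the labels name the compound for EB, so these falls cannot be assigned to differentiation alone. Of 26 cell cycle genes 22 fell and 2 rose, with a median of -0.34 (camera adjusted p = 2.68e-05; 0.0453 with an estimated correlation), which was -0.20 with quantile normalization and -0.52 with arrays centred on their medians. They include AURKA (-0.78 ± 0.043), BUB1 (-0.70 ± 0.038), CCNB1 (-0.40 ± 0.033) and CDK1 (-0.38 ± 0.033). Of 17 cholesterol synthesis genes 14 fell and 1 rose, with a median of -0.50 (adjusted p = 5.60e-05; 0.0540 with an estimated correlation). The changes were -1.13 ± 0.035 for HMGCS1, -1.08 ± 0.032 for FDPS and -1.27 ± 0.042 for STARD4, a sterol carrier gene. IDI1 fell by 1.11 ± 0.040 on its brightest probe set, while 2 of its 4 tested probe sets rose. Of 20 actin and YAP response genes 15 fell and 1 rose, with a median of -0.57 (adjusted p = 7.45e-05; 0.0504 with an estimated correlation). CCN2 and CCN1, secreted targets of YAP, changed by -1.83 ± 0.047 and -1.73 ± 0.047, and CNN2, encoding calponin 2, by -1.06 ± 0.044. TPM1 fell by 0.52 ± 0.032, with 1 of its 5 tested probe sets opposite.

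Lists for p53 targets, hypoxia, dissociation stress, blood cells, mature tissue and housekeeping did not pass camera, with adjusted p = 0.422, 0.151, 0.223, 0.649, 0.427 and 0.223. With fry all of them except housekeeping passed (adjusted p = 6.24e-06, 0.0394, 0.00041, 0.0394, 0.0037 and 0.0753 in the same order). Among p53 targets and inhibitors of cyclin-dependent kinases 9 of 18 rose and 6 fell, with CDKN1C up by 1.68 ± 0.051, GADD45A by 1.23 ± 0.047 and RRM2B changed by -1.33 ± 0.045. Among 24 hypoxia and glycolysis genes 8 rose, VEGFA by 1.35 ± 0.053, and 13 fell, ALDOC by -1.60 ± 0.073 and HK2 by -1.13 ± 0.068. Among 18 stress genes 8 fell, ASNS by -1.05 ± 0.039 and TRIB3 by -1.09 ± 0.083, and 5 rose, HSPA5 by 0.61 ± 0.031. Among 5 blood and immune genes 1 rose, LYZ (at least 1.2-fold), and 1 fell, ITGAM, dim in EB (at least 1.03-fold). LYZ was above the array median on 2 of the 4 EB arrays, both H1. The call of ITGAM was lost without the arrays labelled H9 EB (adjusted p = 0.168) and without H1 EB replicate 1 (adjusted p = 0.0541), undifferentiated H1 replicate 2 (adjusted p = 0.0549) or H9 EB replicate 2 (adjusted p = 0.05002), and with the mean of its probe sets (adjusted p = 0.136), in a range over 18 alternatives from 0.00369 to 0.168. Among 8 mature tissue genes 1 rose, the albumin gene ALB (at least 1.2-fold, above the array median on 2 of the 4 EB arrays, both H1), and 3 fell, MBP by -1.32 ± 0.077 and MYH2 and SYN1, dim in EB, at least 2.1-fold and 1.5-fold. Among 11 housekeeping genes 6 fell and 2 rose, HPRT1 by -0.82 ± 0.044, PGK1 by -0.56 ± 0.047, GUSB by 0.72 ± 0.041 and B2M by 0.43 ± 0.034. The call of GUSB was lost with the mean of its probe sets (adjusted p = 0.0622, the highest of 19 alternatives, from 2.41e-08).

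Some genes given with an exact change were above the array median on only part of the undifferentiated arrays, so that their change rests partly on dim values. These were GASK1B, TBX3, NR2F1, TFAP2A and TFAP2B on 2 of 4, both H1, KLF5, APLNR, FGF8, HAND1 and ZEB2 on 1, and APOA1, TTR, APOB and ISL1 on 3. PLA2G4C was above it on 1 of 4 EB arrays.

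In total 9632 of 14056 genes were called in the mean EB contrast, 4973 higher and 4659 lower, and 1437 and 508 of them changed by at least 1 on the log2 scale. With arrays centred on their medians, chosen after seeing the data, 3637 were higher and 6372 lower, because this scaling moves the median change of all genes from 0.010 to -0.17. Small changes thus have a direction only relative to the scaling. Without the arrays labelled H9 EB only the H1 contrast is left, with 7960 genes called. Of the lists, 16 of 25 passed camera, 12 up and 4 down, and 4 of them, core pluripotency, BMP, neuroectoderm and cell cycle, also with an estimated correlation. Among lists that lost their call the estimate exceeded the preset 0.01 for retinoid and HOX, endoderm, matrix and cholesterol. It was below 0.01 for the others, such as WNT (-0.020), actin and YAP (-0.012) and neural crest (-0.046). A higher correlation among members is therefore not why these others lost it. Counts adjusted over the list alone were equal to those over all genes in 22 lists, and in the other 3 gave 8 FGF-ERK genes higher, 1 neuroectoderm gene lower and 23 cell cycle genes lower.

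For the signature shared by both lines, 3137 genes were higher in EB of both and 2783 lower, 5920 together, where independent lists of these sizes would share 1312 and 1147. In H1 8110 genes were called (4154 higher, 3956 lower) and on the arrays labelled H9 8515 (4441 higher, 4074 lower). The 2 contrasts have no array in common. The share of the H1 EB level above undifferentiated H9 on the arrays labelled H9 EB nevertheless bears on their overlap. Its median was 25.05% in the 5 genes above. APOA1 changed by 7.28 in H1 and 5.90 on the arrays labelled H9, TTR by 7.33 and 4.89, DKK1 by 5.65 and 5.76, NANOG by -0.98 and -0.82, and LCK by -2.39 and -2.38. Another 281 genes were called in both with opposite signs, and log2 changes correlated at r = 0.819 across genes, which are not independent. With arrays centred on their medians the split was 2297 higher and 4200 lower in both lines, 3205 and 5276 in H1, and 3219 and 5823 on the arrays labelled H9.

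**Figure D5:**
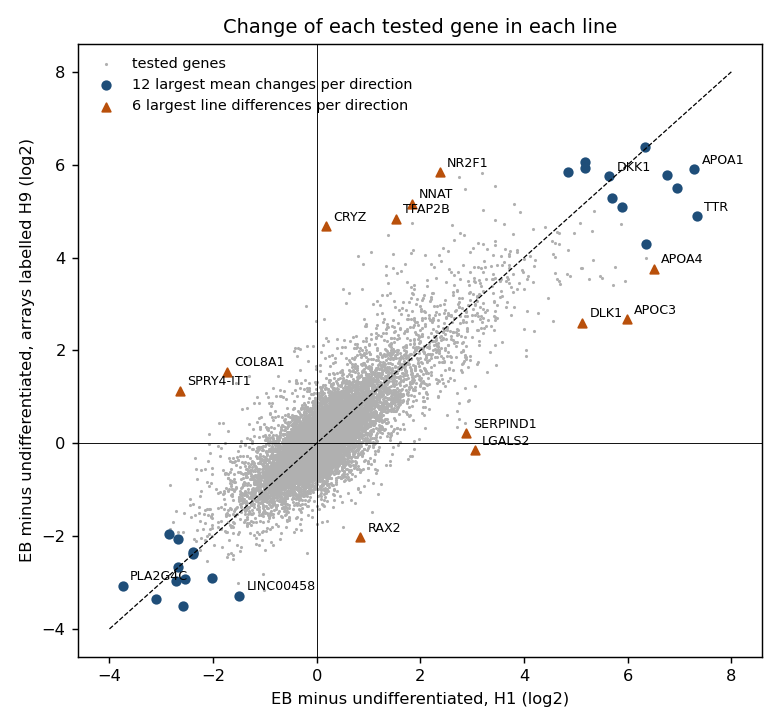
Log2 change of each tested gene in H1 (horizontal) and on the arrays labelled H9 (vertical), with the dashed line marking equal changes. Dark points mark the 12 largest mean changes per direction among genes whose EB and undifferentiated arrays did not overlap in either line, some of them away from the dashed line (TTR by -2.44), and triangles the 6 largest differences between lines per direction.

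The EB effect differed between lines in 3195 genes, 1615 with a higher and 1580 with a lower value on the arrays labelled H9 than in H1 (1284 and 1814 with arrays centred on their medians). The first direction includes CRYZ, NNAT, encoding neuronatin, NR2F1, TFAP2B, SPRY4-IT1 and COL8A1, and all 6 of these were dim in undifferentiated H9. NR2F1 rose by 2.38 in H1 and at least 65.7-fold on the arrays labelled H9, and TFAP2B by 1.52 and at least 18.2-fold (limma adjusted p of the difference = 8.05e-08 and 1.61e-05). In the other direction the apolipoprotein genes APOC3 and APOA4 rose at least 16.8-fold and 31.1-fold in H1, against at least 2.9-fold and 6.7-fold on the arrays labelled H9. DLK1 rose by 5.12 in H1 and by 2.60 on the arrays labelled H9, where its undifferentiated level was already 4259 against 633. At the preset correlation the neural crest and matrix lists had the larger rise on the arrays labelled H9 (camera adjusted p = 7.85e-08 and 1.24e-08), and endoderm in H1 (adjusted p = 0.000980). With an estimated correlation these had adjusted p = 0.0886, 0.190 and 0.190, and all 11 lists that had passed lay between 0.0886 and 0.366. CRYZ is one of the genes that mark the arrays labelled H9 EB, and the count fell to 2031 without H1 EB replicate 1 and 2072 without H9 EB replicate 1.

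In undifferentiated cells 3686 genes differed between lines, 1932 higher in H9 and 1754 lower. Among changes of at least 1 on the log2 scale 135 were higher in H9 and 269 lower, and with the mean of all probe sets of a gene 1111 genes were higher and 1211 lower. TCEAL2 and NLRP2 were much higher in H9, TCEAL2 at least 20.4-fold and NLRP2, an inflammasome family gene, by 4.62 ± 0.095. DLK1 was higher by 2.72 ± 0.094, ZNF681 by 2.60 ± 0.16, TSPYL5 by 2.54 ± 0.13, ZNF717 at least 4.8-fold, NLRP2B at least 3.4-fold and LAMP5 at least 2.0-fold. In the other direction CRYZ was lower in H9 at least 55.1-fold, ZNF680 at least 21.3-fold, TYW3 at least 18.9-fold, NNAT at least 11.8-fold, TRIM61 at least 8.6-fold, CXCL11 at least 6.2-fold and EN2 at least 4.8-fold, and CAT, the catalase gene, by -4.27 ± 0.22, with 1 of the 2 undifferentiated H9 arrays above the array median. Of 26 matrix genes 15 were lower in H9, with a median of -0.43, and of 13 neural crest genes 8 were lower and 1 higher, with a median of -0.59. Of 17 cholesterol genes 11 were higher in H9, with a median of 0.36. These lists passed camera (adjusted p = 1.02e-07, 0.000169 and 1.76e-07), but not with an estimated correlation (adjusted p = 0.238, 0.134 and 0.134). All 7 lists that passed lay between adjusted p = 0.134 and 0.519 with an estimated correlation. The same undifferentiated arrays enter the differences of the EB effect, so these comparisons are not independent.

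Between EB, 2152 genes differed, 1124 higher on the arrays labelled H9 and 1028 lower, and 154 of them by at least 1 on the log2 scale. This count fell strongly whichever EB array was left out, which leaves a lone array on that side of the comparison. The fall does not single out any library. With arrays centred on their medians 793 were higher and 1253 lower.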

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

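The tests of H1 material, of activation and of a sample swap, and the limits they use, were chosen after the result was seen, that of a swap in place of an earlier one on dim signals with the same outcome; the test of the difference between lines was not. The EB effect differed between H9 and H1, by limma's test of the difference itself, in the following genes named by the rule. On the arrays labelled H9 the effect was higher by 4.50 for CRYZ, 3.77 for SPRY4-IT1, 3.47 for NR2F1, 3.33 for NNAT, 3.31 for TFAP2B and 3.27 for COL8A1. It was lower than in H1, by -3.31 for APOC3, -3.20 for LGALS2, -2.86 for RAX2, -2.75 for APOA4, -2.66 for SERPIND1 and -2.52 for DLK1. These are fitted values of log2(value + 16), and all of these genes except DLK1 were dim in at least 1 of the 4 groups, so the sizes are not exact folds. LGALS2, RAX2 and SERPIND1 had low signals, and SERPIND1 lost its call in 8 of 16 alternatives, among them an added value of 1 (adjusted p = 0.136) and leaving out undifferentiated H1 replicate 1 (adjusted p = 0.0804), undifferentiated H1 replicate 2 (adjusted p = 0.0548), H1 EB replicate 1 (adjusted p = 0.112), H1 EB replicate 2 (adjusted p = 0.0925), undifferentiated H9 replicate 1 (adjusted p = 0.108) or H9 EB replicate 1 (adjusted p = 0.107), in a range from 0.00920 to 0.136.

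The 5 genes chosen above were steady in H1, dim in undifferentiated H9 and lower there than in undifferentiated H1 by at least 2 on the log2 scale. They were present on the arrays labelled H9 EB at a median of 25.05% of the H1 EB level, both taken above undifferentiated H9. The median was 18.6% with the array median in place of dim signals. The shares were 31.6% for CRYZ, 25.2% for TYW3, 24.8% for CXCL11 and 18.4% for ZNF680, with TRIM61 at the median. With a limit of 1 on the log2 change in H1 the shares of 9 genes ran from -6.0% to 240%, with 8 above 0. Activation of the 5 genes in differentiating H9 alone is argued against by a check of identity, which 2 of 8 libraries failed. A whole-sample swap is argued against by the highest share of the 5 genes, 31.6%, where H1 EB in their place would give about the full H1 EB level. RNA or cells of H1 in these samples may account for the pattern, but for how much of it stays undecided. A share of 25.05% with no other change would leave genes silent in H1 at 74.95% of undifferentiated H9. TCEAL2, NLRP2B, ZNF717 and LAMP5, dim in H1 in both states, stood at 25.98%, 42.5%, 58.3% and 126%. They changed otherwise or the share is another. Of 14056 genes 9632 were called in the mean EB contrast, so such genes may also change with state and cannot settle this. Earlier conditions asked only for a fall of such genes, which any fall on differentiation meets; the first, undecided, counted MAGI2-AS3, at 192% of undifferentiated H9, and the next, which was met, left it out for its signal of 317 in H1 EB, while a limit on brightness kept LAMP5 out of both.

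Among 3535 tested probe sets without a gene in the annotation used here, 1799 were called between EB and undifferentiated arrays by limma, 1129 higher and 670 lower, a signal outside the gene comparisons.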

How the results depend on the processing

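Centring on array medians and leaving out the arrays labelled H9 EB were chosen after seeing the data; the rest was planned. Counts stayed within 1.5 times with quantile normalization, added values of 1 and 64, either other filter and centring. Averaging a gene's probe sets gave 1646 genes for the difference of the EB effect, 2322 for H9 against H1 undifferentiated and 998 for EB, and turned TGIF1 to 0.099. Testing 25802 probe sets one by one gave 16346 for the mean EB contrast, 13293 for H1, 14245 for H9, 5584 for undifferentiated lines and 9411 in both lines, since more features were tested. Without trend and robust, 2015 genes differed in EB effect and 894 between EB. A minimum log2 change of 1 left 1945, 2004 and 2180 for the mean, H1 and H9, 552 for the difference, 404 and 154 for H9 against H1, and 1347 in both lines. Camera with an estimated correlation left 4 lists and fry 24. Except where a construction is named, the cause was not tested. Leaving out single arrays gave 9009 to 9321 genes for the mean contrast, 6891 to 8301 for H1, 7297 to 8612 for H9, 5190 to 5612 in both lines, 2031 to 3122 for the difference (lowest without H1 EB replicate 1, 2072 without H9 EB replicate 1), 2543 to 3367 for undifferentiated lines, and 717 to 2403 for EB (717 and 928 without H9 EB replicates 1 and 2, 749 and 925 without H1 EB replicates 1 and 2), and 15 to 16 lists; a lone array was then assumed to vary like the other groups. Without the arrays labelled H9 EB 7960 genes, 3370 between undifferentiated lines and 13 lists passed. Deviations of same-numbered replicates correlated at -0.046 to 0.054, so the numbers share only a name; with a replicate block the counts were 9542, 8041, 8468 and 5881 for the mean, H1, H9 and both lines, 3070 for the difference, and 3547 and 2036 for H9 against H1, and 16 lists passed. Signal over background limits dim genes, whose folds are bounds.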

Other observations

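The gene families and the tests of undifferentiated H1 were chosen after the data were seen, that on endoderm genes after 3 earlier forms, of which 2 had argued against its explanation and 1, on whether ranges overlap, had left it open, and the count over splits of the arrays was not. Of 11 tested apolipoprotein genes 8 rose in EB and 1 fell, with a median of 1.83, which was 1.92 with quantile normalization and 1.65 with arrays centred on their medians. All 3 fibrinogen chains rose, with a median of 5.32. Of 28 protocadherin genes 16 rose and 2 fell, with a median of 0.63, while 7 of 12 chemokine ligand genes fell and 3 rose, with a median of -0.69. Medians of these families kept their sign in all 3 scalings. Of 60 ribosomal protein genes 50 fell and 3 rose, with a median of -0.19, but the median was -0.027 with quantile normalization, against a median of all genes of -0.055 there. With arrays centred on their medians the ribosomal median was -0.36, against -0.17 for all genes. Of 21 core histone genes 13 were lower in undifferentiated H9 than in H1, with medians of -0.75, -0.71 and -0.74 in the 3 scalings.

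Of 13 neural crest genes 8, and of 26 matrix genes 15, were lower in undifferentiated H9 than in undifferentiated H1, with list tests that did not pass with an estimated correlation (adjusted p = 0.134 and 0.238). Between-array scaling as the whole reason is argued against by the median difference of -0.45 that was left with quantile normalization, against -0.51 as deposited. For the shares that follow, only list members were used that rose in H1 EB by more than 1 on the log2 scale at a limma adjusted p under 0.05. A share of cells of every EB type in the H1 cultures, as the whole reason, is argued against by endoderm genes, which stood at a median of -0.55% of their H1 EB level above undifferentiated H9 (SD 2.08, 14 genes, from -4.82% to 5.23%), with AFP at 0.45% and APOA2 at -0.45%. Such a share would bring them to the level of neural crest genes, at a median of 12.2% (7 genes, from -11.1% to 30.9%) or of matrix genes, at 8.28% (19 genes, from -10.7% to 28.9%), although 1 neural crest and 8 matrix genes lay below the highest endoderm gene. The neural crest and matrix lists were picked for their difference between the lines, so their positive medians follow from that choice. A subset of H1 cells with neural-crest-like expression, or a difference between the lines themselves, may remain as hypotheses and was not tested.

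The split of the 8 arrays into EB and undifferentiated gave 7766 called genes in a fit of 2 groups, and the highest of the other 34 splits, that of H9 against H1, gave 22. The real split was 1 of 35 with as many, which is below the limit set before and the lowest share that 35 splits can give. Any other split mixes tight groups of arrays, which raises the spread within its sides. The count therefore shows that the arrays part by state, and it cannot tell differentiation from medium, attachment or the compound.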
